A study of Homo sapiens with 12 samples.

How the data were processed

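RNA was sequenced from human preadipocytes, the fat-forming precursor cells of adipose tissue, isolated from abdominal subcutaneous fat. The cells had been made senescent (permanently arrested after damage) with 20 Gy of X-rays. At 30 days they received the solvent DMSO or 800 nM dasatinib for 24 h, were washed 4 times, and were kept for 3 more days. Per the labels' protocols, RNA was extracted with Trizol and chloroform and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA. The 12 libraries comprise 6 DMSO and 6 dasatinib libraries, numbered 1 to 6 in each group by the labels.

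The values are whole-number read counts per gene, deposited by the authors as 1 table with no normalization. Per the submitters' processing notes, the tools included fastp 0.20.1 and STAR 2.7.9a with genome build GRCh38. The counting tool, its strand setting and the annotation release are not given in the sources used here. Reads of a gene and of an overlapping or antisense partner therefore may not be separated, and reads of near-identical copies, such as those of the actin and tubulin families, may be split or lost. The header line of the table has a doubled tab before its last name, and the last column of values was given that name. That name belongs to dasatinib replicate 6, and the edgeR counts of genes without pairing and in the paired, GC-corrected fit, and the camera count of lists without pairing, were also made without replicate 6. The number of columns of per-sample values left unused was 0.

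The table had 60662 rows of versioned Ensembl gene IDs, of which 60402 matched a symbol table when versions were ignored. The number of rows that name no gene was 0. Y-linked genes, XIST and TSIX were left out of every step, which kept 60105 rows. Gene positions are those of GENCODE 29 on GRCh38. Total counts per library ran from 16070291 to 52637606. Reads carry no molecular identifiers, so limits from counts cover counting error only.

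The comparison was dasatinib against DMSO. The test fixed before the data were examined was edgeR 4.0.16's quasi-likelihood test in R 4.3.3, with treatment as the only term, TMM scaling, edgeR's default filter (a minimum count of 10) and a Benjamini-Hochberg adjusted p threshold of 0.05, 2-sided. It tested 15068 genes. A set test (camera in limma 3.58.1, preset correlation 0.01) was run on 27 gene lists written before the data were examined, of which 26 had at least 5 tested members. camera was repeated with an estimated correlation, and fry was run as well. Library composition was compared by 2-sided exact permutation tests, adjusted over 5 measures. Expression is given as CPM, a gene's share of its library's TMM-scaled total, computed from the counts, as mean ± SD.

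The labels do not say that a number marks a donor. Deviations from the group mean in libraries of the same number correlated across all genes tested at 0.21 to 0.81 (Pearson; genes are not independent replicates), above the 0.1 set as the threshold for each pair. In 5 of 6 numbers the own number gave the highest correlation, and in replicate 6 it did not (0.21 against 0.25). The highest correlation with another number was 0.15 to 0.38, also above 0.1, so passing that threshold alone does not show pairing. Over genes with a mean above log2 CPM 2 the lowest value was 0.03, for replicate 6, and after the GC correction described next it was 0.36. Over those genes the own number was highest in 4 of 6 numbers, not in replicates 5 and 6, and in 6 of 6 after that correction. The numbers were therefore treated as pairing the libraries, and a fit with the number as a block was planned beside the fit without it. If numbers do not mark separate donors or cultures, p-values measure only the spread between these libraries.

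A further fit was chosen after the data were seen, because the libraries differed in how counts followed the GC content of genes. For each library, a robust spline (5 degrees of freedom) of the deviation from the gene mean on the GC share of the longest transcript was used as an offset, together with the block. It tested 14975 genes. The spline has an intercept, so it also sets the level of each library, and replacing TMM by DESeq2's size factors (RLE) cannot change this fit. The scaling was therefore varied with the spline centred to 0 in each library, so that TMM or RLE sets the level. The words rose and fell are used of genes past the threshold in this paired, GC-corrected fit, and of lists past it in the set test. Fold changes are log2 values of that fit ± SE unless another is named.

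The procedure was tested on simulated data with the means, library sizes, dispersions and GC trends of these libraries, in 5 simulations with 200 changed genes each and a median of 14736 genes. For dasatinib against DMSO the paired, GC-corrected fit recovered 58.9% of 1.5-fold, 75.8% of 2-fold and 97.2% of 4-fold changes, and 6.7% of its calls were false. The fit with the block alone recovered 26.6%, 67.3% and 96.2%, and the fit without it 1.5%, 28.2% and 76.7%. The counts were drawn from the paired, GC-corrected model itself, so its lead over the other fits is built in. The simulation therefore does not test that model on the real libraries. On the real counts the fit with the block alone called 0 genes, so the simulated rates may not carry over.

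Genes were named by a rule written before the data were examined. It takes up to 8 genes in each direction by fold change, with a mean of at least log2 CPM 1, past the threshold in the fits without and with the block, 16 genes fixed in advance, and up to 3 members of each list with the smallest p. It gave 83 genes. The same rule applied to the paired, GC-corrected fit added 12, and 26 more were named after their values were seen (ACTG1, FLNA, CCN1, SRF, LMOD1, 7 tubulin genes, CXCL1, CXCL2, ICAM1, TNFAIP2, SQSTM1, DRAM1, HMOX1, SFRP2, AEBP1, GPNMB, INHBA, THBS1, CLU and IL11). Some genes that the rule takes are counted among these but are not reported here. Alternatives covered the block, scaling, filters, DESeq2 1.42.0, limma-voom with and without quality weights, and the libraries left out.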

Results

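The counts per gene of 12 libraries from irradiated, senescent human preadipocytes were compared, 6 after DMSO and 6 after dasatinib, an inhibitor of SRC-family, ABL and other tyrosine kinases that is used to kill senescent cells. The comparison addresses how the cells that remain after dasatinib differ from solvent-treated senescent cells. Total counts were 31044095, 41769092, 37795576, 48229334, 44644865 and 52637606 for DMSO replicates 1 to 6. They were 41944385, 36169805, 34478125, 44404250, 16070291 and 38057474 for dasatinib replicates 1 to 6.

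After dasatinib, 7 of 30 SRF and YAP target genes and 6 of 40 extracellular matrix genes rose. Of 25 genes on a list of inflammatory cytokines and chemokines 4 fell, of which ICAM1 is an adhesion molecule. ACTA2, smooth muscle actin (ENSG00000107796.13, chromosome 10, 88935074 to 88991339), rose from 455 ± 117 to 1112 ± 303 CPM (SD, n = 6), a log2 fold change of 1.28 ± 0.15. CNN1, the actin-binding protein calponin 1 (chromosome 19, 11538717 to 11550323), rose from 58.4 ± 18.1 to 110.7 ± 23.6 CPM, by 0.97 ± 0.12. CSF3, a granulocyte growth factor, fell by 2.18 ± 0.36, at a low level of 0.778 ± 0.580 CPM in DMSO. ALDH1A3, an enzyme of retinoic acid synthesis (chromosome 15, 100877714 to 100916626), went from 427 ± 295 to 245 ± 152 CPM and fell by 0.75 ± 0.09. ACTA2, CNN1, CSF3 and ALDH1A3 each moved one way in 6 of 6 pairs.

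These calls come from the paired, GC-corrected edgeR fit, chosen after the data were seen, in which 65 genes rose and 45 fell of 14975 tested. The edgeR fit fixed beforehand, without pairing or correction, called 0 of 15068 genes (256 at an unadjusted p under 0.05, smallest adjusted p = 0.81). With the block alone edgeR also called 0 (1003 at an unadjusted p under 0.05, smallest adjusted p = 0.076). DESeq2 called 1 gene, ACTA2, without the block (503 at an unadjusted p under 0.05) and 112 with it, of which 69 were among the 110. Of the genes said here to have risen or fallen, DESeq2 with the block did not call FLNA, SRF, INHBA, HMOX1, MMP2 and C1R (adjusted p = 0.063, 0.40, 0.63, 0.062, 0.081 and 0.12). It did not call the tubulin genes TUBB2A and TUBB4B either (adjusted p = 0.13 and 0.48). The corrected fit called 0 genes without replicate 2 and 0 without replicate 4, 34 without replicate 1 and 45 without replicate 3. With the GC curve centred so that TMM or RLE set the library level, 72 and 74 of the 110 remained. The 110 were checked under 13 alternatives that kept pairing and the GC correction. ACTA2, CNN1 and ALDH1A3 passed in 11 of them, and CSF3 and MMP1 in 6. IL1B, ICAM1 and MKI67 passed in 5, C1R in 3 and GDF15 in 2.

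**Figure D1:**
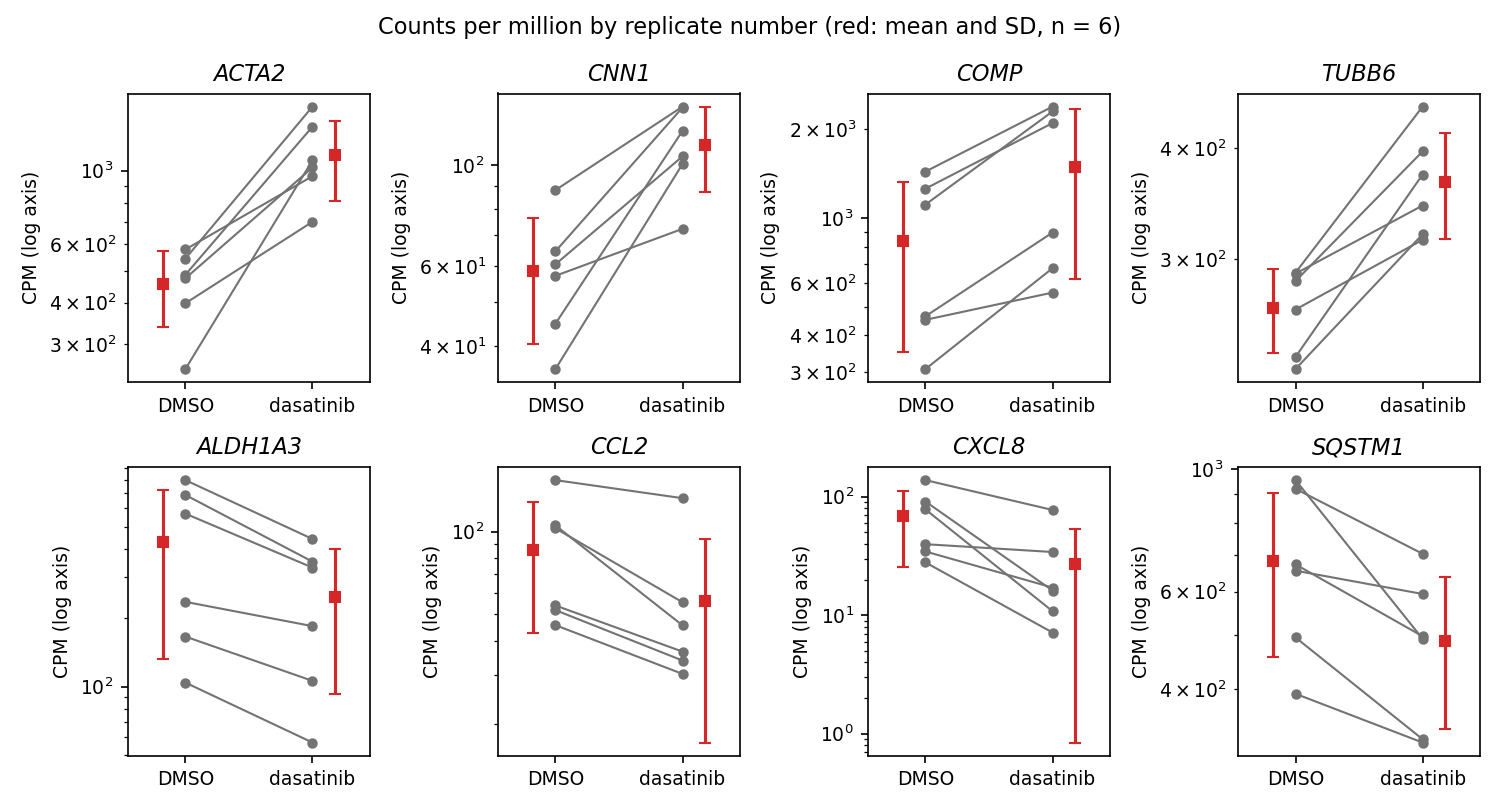
CPM (log axis) of 8 genes in each library, with grey lines joining the DMSO and dasatinib libraries of the same replicate number and red squares and bars for the mean and SD (n = 6). All 8 genes move one way in 6 of 6 pairs, and ACTA2 goes from a mean of 455 to 1112 CPM. CXCL8 did not pass the threshold over all genes (adjusted p = 0.077).

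Targets of SRF and YAP, regulators that respond to actin and cell tension, rose as a list of 30 tested genes (camera adjusted p = 2.19e-21, and adjusted p = 0.0099 with an estimated correlation). With fry the list's adjusted p was 0.035 without pairing and 0.0050 with pairing and GC correction. With the preset correlation and no block, swapping treatment within replicate numbers moved up to 10 of the 26 lists. A preset camera p-value alone is therefore weak evidence that a list moved, here and below. In the paired, GC-corrected fit 7 of the 30 rose, 0 fell and 23 did not pass, and 16 rose when adjusted over the list alone. The fit without pairing or correction called 0 of them over all genes and 7 adjusted over the list alone. ACTB and ACTG1, the cytoplasmic actins, rose by 0.53 ± 0.06 and 0.52 ± 0.06, with ACTB going from 5788 ± 484 to 8422 ± 1332 CPM. FLNA, an actin crosslinker, rose by 0.38 ± 0.05, CCN1, a secreted YAP target, by 0.38 ± 0.05, and SRF itself by 0.35 ± 0.06. With pairing, GC correction and an estimated correlation the list's adjusted p = 0.11.

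The list of pericyte and smooth muscle markers also rose (13 tested, camera adjusted p = 3.69e-11, and adjusted p = 0.014 with an estimated correlation). Its 3 members that rose, ACTA2, CNN1 and LMOD1 (0.75 ± 0.12), encode parts of the contractile apparatus, and 10 did not pass. ACTA2 and CNN1 are also on the list of SRF and YAP targets, so the rises of these lists are not independent. Adjusted over the list alone, 5 rose. With fry the list's adjusted p was 0.13 without pairing and 0.0096 with pairing and GC correction. MYH11, smooth muscle myosin, had 1.53 ± 0.34 (adjusted p = 0.092), with 6.89 CPM in dasatinib replicate 5 against 1.32 to 2.28 in the other dasatinib libraries. The paired, GC-corrected fit gave the list an adjusted p = 0.12 with an estimated correlation.

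Extracellular matrix genes rose as a list of 40 (camera adjusted p = 4.29e-10, and adjusted p = 0.047 with an estimated correlation). With fry the list's adjusted p was 0.26 without pairing and 0.043 with pairing and GC correction. In the paired, GC-corrected fit 6 rose, 0 fell and 34 did not pass. Adjusted over the list alone, 16 rose and 1 fell, and with an estimated correlation the list's adjusted p = 0.17. COL6A3, a collagen VI chain, rose by 0.62 ± 0.09, BGN, the proteoglycan biglycan, by 0.52 ± 0.06, and THBS1, thrombospondin 1, by 0.44 ± 0.08 from 8269 ± 2354 to 11348 ± 3021 CPM. COMP, a cartilage matrix protein outside the list (chromosome 19, 18782773 to 18791314), rose from 838 ± 485 to 1484 ± 861 CPM, by 0.86 ± 0.10. SFRP2, AEBP1, MGP and GPNMB, also not among the 6 list members that rose, rose by 0.84 ± 0.11, 0.83 ± 0.10, 0.93 ± 0.16 and 0.73 ± 0.09. COL1A1, a collagen I chain, had 0.26 ± 0.07 (adjusted p = 0.18), and FN1, fibronectin, 0.38 ± 0.07 (adjusted p = 0.061). With the GC curve centred, BGN alone of the 6 remained with both TMM and RLE, and COL6A3 and THBS1 had adjusted p = 0.054 and 0.069 with TMM.

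Cytokines and chemokines of the senescence-associated secretory phenotype (SASP), the factors that senescent cells release, fell as a list of 25 (camera adjusted p = 2.76e-08). The call was lost with an estimated correlation (adjusted p = 0.17), passed with the block and an estimated correlation (adjusted p = 0.047), and was lost again with the GC correction added (adjusted p = 0.17). With fry the list's adjusted p was 0.48 without pairing and 0.031 with pairing and GC correction. In the paired, GC-corrected fit 4 fell, 0 rose and 21 did not pass, and adjusted over the list alone 15 fell and 1 rose. CCL2, a monocyte attractant (chromosome 17, 34255218 to 34257203), fell from 85.6 ± 42.7 to 55.7 ± 38.6 CPM, by 0.68 ± 0.12. IL1B, interleukin 1 beta, fell by 0.74 ± 0.14, ICAM1, an adhesion molecule, by 0.36 ± 0.06, and the other was CSF3. The neutrophil attractants CXCL8, CXCL1, CXCL2 and CXCL3 had -1.40 ± 0.30, -1.29 ± 0.26, -1.23 ± 0.27 and -1.29 ± 0.30, and none of these 4 passed over all genes (adjusted p = 0.077, 0.069, 0.082 and 0.10). IL6, a central SASP cytokine, had 0.14 ± 0.09 (adjusted p = 0.56) at 275 ± 70.9 CPM in DMSO and 305 ± 81.2 after dasatinib, and IL11, a fibrosis-linked cytokine, had 0.71 ± 0.15 (adjusted p = 0.073). With the GC curve centred, CCL2 and CSF3 remained with both TMM and RLE, and IL1B and ICAM1 did not pass with TMM (adjusted p = 0.051 and 0.060).

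NF-kB targets, which share several chemokines with that list, fell as well (26 tested, camera adjusted p = 5.09e-10). The call was lost with an estimated correlation (adjusted p = 0.17 without the block, 0.051 with it, 0.17 with the block and GC correction). With fry the list's adjusted p was 0.47 without pairing and 0.031 with pairing and GC correction. In the paired, GC-corrected fit 4 fell (CCL2, IL1B, ICAM1 and TNFAIP2, the last by 0.41 ± 0.06) and 22 did not pass, and adjusted over the list alone 12 fell. With the GC curve centred TNFAIP2 did not pass with TMM (adjusted p = 0.052). TNFAIP3, a feedback inhibitor of NF-kB, had -0.40 ± 0.10 (adjusted p = 0.11).

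The other SASP groups did not move as lists. Of 23 proteases and inhibitors (camera adjusted p = 0.67), MMP2, a gelatinase, rose by 0.35 ± 0.05 and MMP1, a collagenase, fell by 0.80 ± 0.15, while 21 did not pass. MMP1 in DMSO replicate 4 stood at 1.75 CPM against 22.2 to 71.2 in the other DMSO libraries. MMP3, a stromelysin, had 0.08 ± 0.12 (adjusted p = 0.84). Of 32 growth factors and binding proteins (camera adjusted p = 0.67), INHBA, an activin subunit, rose by 0.47 ± 0.06 and GDF15, a stress-induced cytokine, fell by 0.33 ± 0.06, while 30 did not pass. Adjusted over the list alone, 4 proteases rose and 2 fell, and 5 growth factors rose and 4 fell. With the GC curve centred, MMP2 and GDF15 did not pass with TMM (adjusted p = 0.060 and 0.069).

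Markers of the senescent arrest did not move as a list of 20 (camera adjusted p = 0.61). CDKN1A, the p21 cell-cycle inhibitor, had -0.21 ± 0.05 (adjusted p = 0.12) and CDKN2A, the p16 locus, -0.0017 ± 0.052 (adjusted p = 0.995). CDKN2A was higher in 4 pairs and lower in 2. It went from 101 to 122 CPM in replicate 5 and from 122 to 85.9 CPM in replicate 6. LMNB1, lamin B1, had 1.18 ± 0.44 (adjusted p = 0.31) at 0.4 CPM in DMSO. Proliferation genes rose as a list of 29 (camera adjusted p = 1.58e-08). The call was lost with an estimated correlation (adjusted p = 0.17) and passed with the block and an estimated correlation (adjusted p = 0.046), and with the GC correction added the adjusted p = 0.12. MKI67, a marker of cycling cells, rose by 1.75 ± 0.31, from 0.606 ± 0.647 to 1.97 ± 1.98 CPM, and RRM2, a ribonucleotide reductase subunit, by 0.997 ± 0.15, from 1.30 ± 0.76 to 2.63 ± 1.64 CPM. The other 27 did not pass, and 5 rose adjusted over the list alone. MKI67 did not pass with the GC curve centred and TMM (adjusted p = 0.053).

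Targets of p53 fell as a list of 28 (camera adjusted p = 0.0056, and adjusted p = 0.17 with an estimated correlation). GDF15 was the member that fell, 27 did not pass, and 4 fell adjusted over the list alone. That fall of GDF15 passed in 2 of the 13 alternatives to the paired, GC-corrected fit. Pro-apoptotic genes fell as a list of 26 (camera adjusted p = 0.029, and adjusted p = 0.17 with an estimated correlation) with 0 members past the threshold. TNFRSF10B, a death receptor on both lists, had -0.23 ± 0.05 (adjusted p = 0.11). Without dasatinib replicate 5 the p53 and pro-apoptotic lists did not pass (adjusted p = 0.067 and 0.14), and the pro-apoptotic list did not pass without replicate 3, 5 or 6 either (adjusted p = 0.0977, 0.157 and 0.0981). With an estimated correlation the p53 list had an adjusted p of 0.047 with the block and 0.17 with the block and GC correction, and the pro-apoptotic list 0.19 and 0.27. The 23 anti-apoptotic genes did not move (camera adjusted p = 0.89), and BCL2L1, which encodes BCL-xL, had -0.19 ± 0.05 (adjusted p = 0.18). The 30 kinases and ephrins bound by dasatinib or linked to it did not move either (camera adjusted p = 0.18), with SRC at 67.5 ± 13 and 66.7 ± 13.3 CPM (0.0058 ± 0.052, adjusted p = 0.98) and PDGFRB at 0.18 ± 0.09 (adjusted p = 0.43).

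Genes of the NRF2 oxidative stress response fell as a list of 24 (camera adjusted p = 0.0057, and adjusted p = 0.59 with an estimated correlation, 0.15 with the block added and 0.22 with the block and GC correction). HMOX1, heme oxygenase 1, fell by 0.40 ± 0.06 and 23 did not pass. Outside the lists, SQSTM1, the autophagy receptor p62 (chromosome 5, 179806398 to 179838078), fell from 682 ± 224 to 489 ± 150 CPM, by 0.45 ± 0.05, and DRAM1, a p53-induced regulator of autophagy, by 0.52 ± 0.06. Interferon-stimulated genes fell as a list of 31 with 0 members past the threshold (camera adjusted p = 0.046, and adjusted p = 0.64 with an estimated correlation). That list did not pass with RLE scaling, no filter or the stricter filter (adjusted p = 0.057, 0.075 and 0.27), nor without replicate 2, 3, 4 or 6 (adjusted p = 0.17, 0.17, 0.998 and 0.11). With an estimated correlation its adjusted p was 0.65 with the block and 0.62 with the block and GC correction. Complement genes, 15 tested, did not pass without the block (camera adjusted p = 0.055) and rose with it (adjusted p = 9.23e-04). With an estimated correlation the adjusted p was 0.17 without the block, 0.047 with it, and 0.17 with the block and GC correction. CLU, clusterin, rose by 0.56 ± 0.09 and C1R, a protease of the classical pathway, by 0.50 ± 0.09, while 13 did not pass. With the GC curve centred C1R did not pass with TMM (adjusted p = 0.060). The complement list also passed without the block under RLE scaling and without replicate 1, 4 or 5 (adjusted p = 0.049, 0.043, 0.030 and 0.026).

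**Figure D2:**
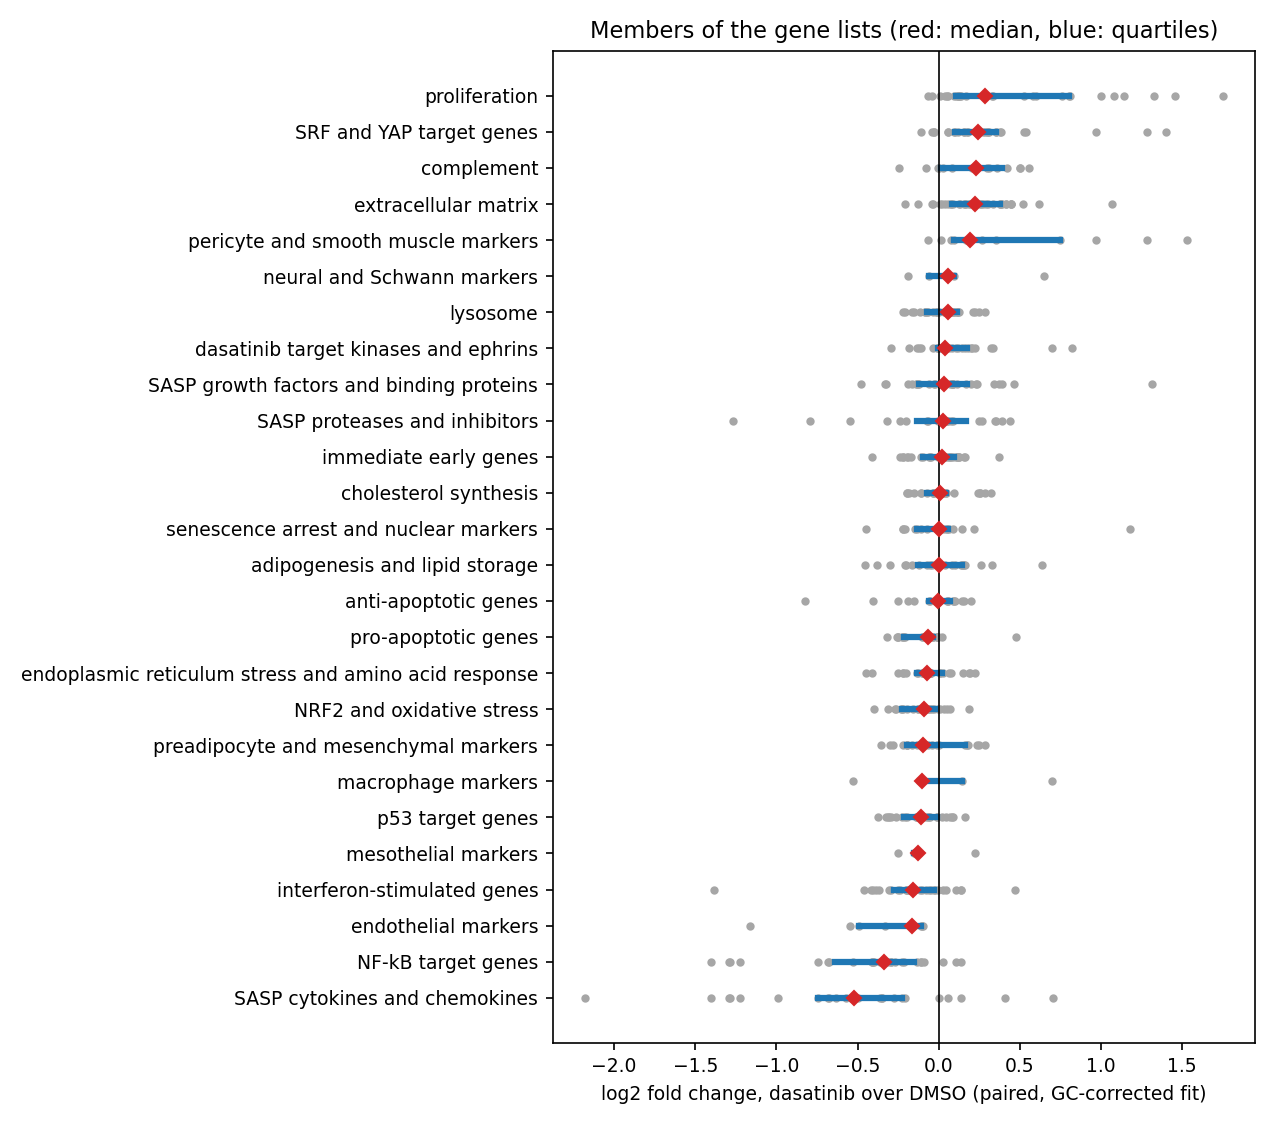
log2 fold change of dasatinib over DMSO in the paired, GC-corrected fit for the members of 26 gene lists, with grey points for genes, red diamonds for medians and blue bars for quartiles. The medians run from -0.52 for SASP cytokines and chemokines to 0.28 for proliferation.

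The remaining lists did not pass in camera. The adjusted p was 0.67 for 32 immediate early genes, 0.89 for 24 adipogenesis and lipid storage genes, 0.36 for 21 preadipocyte and mesenchymal markers, 0.89 for 25 cholesterol synthesis genes, 0.33 for 26 genes of endoplasmic reticulum stress and the amino acid response, and 0.67 for 29 lysosome genes. The adipogenesis list passed without replicate 5 (adjusted p = 0.026). Median, mean and test differed in sign for 7 lists that did not pass (SASP proteases, senescence arrest, anti-apoptotic, immediate early, adipogenesis, preadipocyte and macrophage). In all, camera moved 11 lists of 26 without the block (4 up, 7 down) and 12 with it. With fry, pairing and GC correction the preadipocyte and mesenchymal list passed (adjusted p = 0.031). So did those of proliferation (0.018), p53 targets (0.031), complement (0.031) and endothelial markers (0.043). Without pairing none of these passed with fry (adjusted p = 0.42 to 0.71). With pairing and GC correction the pro-apoptotic, NRF2 and interferon lists did not pass with fry (adjusted p = 0.082, 0.079 and 0.48).

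Of the lists of markers of other cell types, some were scarce and some held abundant genes. Over 1 CPM (median over libraries) were 2 of 18 macrophage, 1 of 16 lymphocyte, 6 of 16 endothelial, 4 of 12 mesothelial, 4 of 12 neural and Schwann, and 12 of 14 pericyte and smooth muscle genes. The most abundant gene was TINAGL1 of the pericyte list, at 839.7 CPM, KRT18, a keratin, of the mesothelial list, at 598.7 CPM, and TEK, an angiopoietin receptor, of the endothelial list, at 128.8 CPM (TINAGL1 and TEK were named after their values were seen). The macrophage list had 5 of 18 genes tested (camera adjusted p = 0.89), the mesothelial list 5 of 12 (0.67), the neural and Schwann list 5 of 12 (0.61), and the lymphocyte list 1 of 16, too few for a test. The endothelial list fell with 9 of 16 genes tested (camera adjusted p = 0.029, and adjusted p = 0.16 with an estimated correlation), with 0 members past the threshold. It did not pass without dasatinib replicate 5 or without replicate 2, 5 or 6 (adjusted p = 0.067, 0.065, 0.11 and 0.098), nor with no filter or the stricter filter (adjusted p = 0.22 and 0.23), nor with the GC correction and no block (adjusted p = 0.069). With an estimated correlation its adjusted p was 0.11 with the block and 0.17 with the block and GC correction.

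Dasatinib replicate 5, the library with the lowest total, held transcripts of fast skeletal muscle and of keratinocytes. The 13 genes of a fast muscle list, written after the data were seen, summed to 6376 CPM there, against 3.07 to 31.9 in the other 11 libraries. ACTA1, skeletal muscle actin, stood at 1488 CPM and KRT5, a basal keratin, at 390 CPM. Without that library the fit without pairing called 0 genes (256 at an unadjusted p under 0.05) and the paired, GC-corrected fit 123, with 92 of the 110 among them.

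Libraries also differed in GC trend within both groups. The Spearman correlation across genes between a gene's deviation from its mean and its GC content ran from -0.73 to 0.72 (8109 genes, which are not independent replicates) and was -0.03 ± 0.54 in DMSO and -0.15 ± 0.67 after dasatinib (exact permutation p = 0.80, n = 6). The first principal component held 44.7% of the variance. Its 5 libraries with positive scores were the 5 with a positive GC trend.

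**Figure D3:**
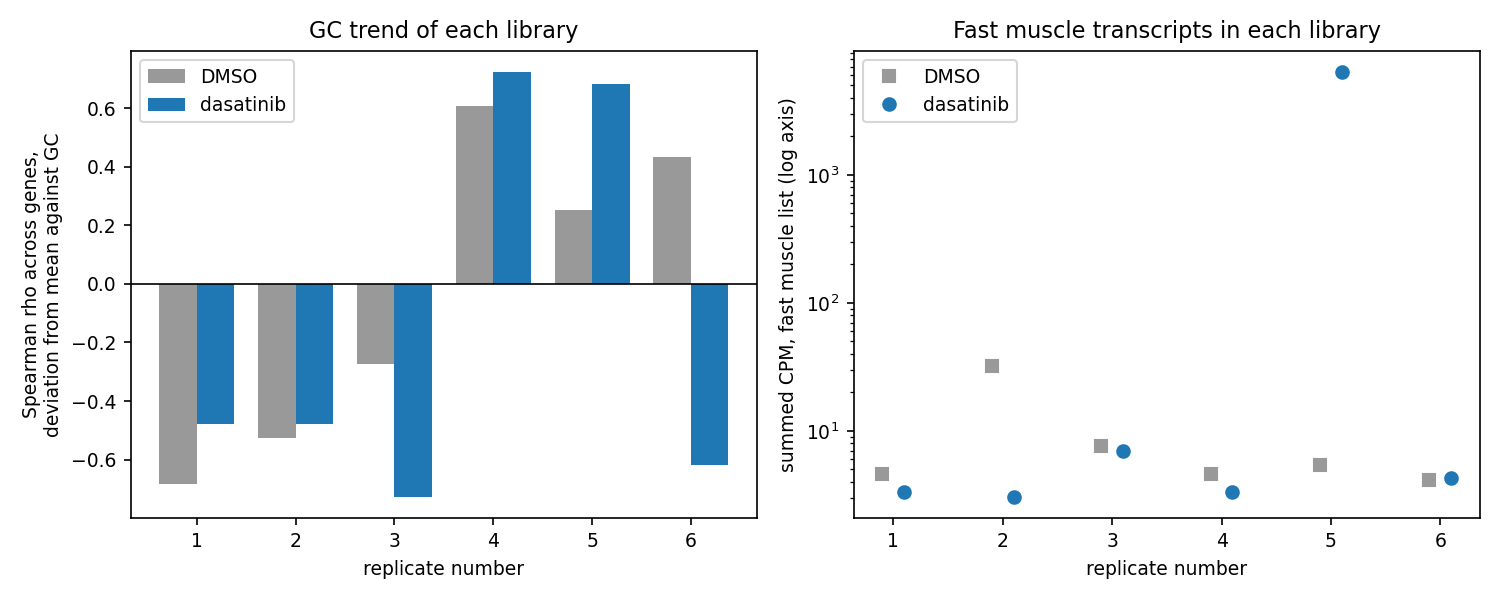
Left, Spearman rho across genes of the deviation from the mean against GC content in each library, by replicate number. Right, summed CPM (log axis) of the fast muscle list in each library, with dasatinib replicate 5 at 6376 and the others between 3.07 and 31.9.

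None of the 5 measures of library composition passed the exact permutation test after adjustment. The 20 most abundant genes took 18.9 ± 0.9% of counts in DMSO and 20.6 ± 0.9% after dasatinib (n = 6, exact permutation p = 0.013, adjusted p = 0.065), higher in 6 of 6 pairs. Without replicate 1 the difference passed (exact permutation adjusted p = 0.040). Total counts were 42.7 ± 7.67 M in DMSO and 35.2 ± 10.1 M after dasatinib (exact permutation adjusted p = 0.43, n = 6), and mitochondrial transcripts took 4.31 ± 0.39% and 4.29 ± 0.37% (exact permutation adjusted p = 0.93, n = 6). Genes detected were 22777 ± 511 and 22225 ± 966 (exact permutation adjusted p = 0.43, n = 6) and ribosomal protein transcripts took 2.92 ± 0.70% and 2.60 ± 0.65% (exact permutation adjusted p = 0.54, n = 6).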

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

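The tests on muscle and keratin reads, on the shift by the GC correction, on replicate 5 and on pericyte markers were chosen after their results were seen. The dispersion test and the counts over other splits were written before.

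Dasatinib replicate 5 stood apart from its group in total count (16.1 M against 34.5 to 44.4 M). In it the fast muscle list summed to 6376 CPM (3.07 to 31.9 in the other 11 libraries) and the keratinocyte list to 724 CPM (1.85 to 40.6), with 0.347% of counts on processed pseudogenes (0.0501 to 0.0729%), and a trace of both lists stood out in DMSO replicate 2, at 31.9 CPM against 4.12 to 7.65 for muscle and 40.6 against 2.96 to 5.64 for keratinocytes. A response to dasatinib would raise the list in the other 5 dasatinib libraries, whose median was 0.67 times that of DMSO. Human skeletal muscle would bring slow-fibre and other abundant transcripts, and their median excess was 0.12% of that of the fast list, with MB at 1.31 and TNNI1 at 0 CPM, which allows up to 0.187 CPM. Reads of another organism stay open and may be the source, since such reads would fall on processed copies, and the pseudogene share was 4.76 times the highest of the other 11 libraries, but no other genome was used here.

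The count of called genes went from 0 with the block to 110 with the GC correction added. A GC trend that adds spread would lower the dispersion when removed, and on the same 14975 genes the common dispersion fell to 0.56 times its value. The curve, with its intercept, was fitted to these same libraries, so a fall was built in. Its size shows how much spread the curve removed, but not that GC content was the source. A correction that itself shifts the called genes would move them by more than their SE. The median shift was 0.22 SE, with the median absolute fold change of the 110 at 0.49 with and 0.49 without the correction and the median SE at 0.070 and 0.108. The spread added by the GC trend therefore stays a candidate explanation that the dispersion test cannot decide. The level that the GC curve sets also matters, as 72 of the 110 calls remained with the curve centred and TMM.

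Among the 110 paired, GC-corrected calls were 7 SRF and YAP targets and 6 matrix genes that rose. Also among them were 4 genes of the cytokine and chemokine list that fell (CCL2, IL1B, CSF3 and ICAM1, an adhesion molecule). Foreign reads in dasatinib replicate 5 would make the changes shrink without that number, and the median ratio without it was 0.99. That median cannot show an effect on a few genes. JPH2, 1 of the 110, stood at 39.1 CPM in that library against 7.66 to 14.2 in the other dasatinib libraries. ACTA2, CNN1 and LMOD1 stood at 1356, 118.9 and 85.1 CPM there. Each was higher in another dasatinib library, at 1559 in replicate 2, 134.4 in replicate 1 and 115.3 in replicate 6. A larger share of pericytes or smooth muscle cells could raise their markers outside the contractile apparatus about as ACTA2, and the median of 7 such markers was 0.17 (quartiles 0.09 to 0.23) against 1.28 for ACTA2. That test cannot decide, since markers that the other cells also express would rise less. TINAGL1, 1 of the 7, had a median of 839.7 CPM over the libraries. A larger share of such cells therefore stays open too. A response of the cells to dasatinib, or survival of cells that had such expression before, stay open and were not tested, since cell numbers and cells before treatment were not analysed here. Of the 32 swaps of treatment within replicate numbers, 1, the real one, gave 110 genes and the highest other gave 0. This argues against chance, but 1 of 32 is the smallest share that these swaps can give. The fit was also chosen after the data were seen, so chance is not excluded for that count.

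For the fits fixed beforehand the real count of genes was 0, which every split reaches (100 of 100 drawn splits without the block, highest other 3881, and 32 of 32 swaps with it, highest other 0), so these counts say nothing about chance. The split with 3881 genes had the largest difference in mean GC trend of the 99 other splits and put the 5 libraries with a positive trend on one side, so it follows that structure of the libraries. For the 11 lists without the block, 2 of 100 splits, the real one included, moved as many (highest other 11). Of the 32 swaps within replicate numbers 1, the real one, did so (highest other 10). Both shares are small, but other labelings moved as many or nearly as many lists, so chance is not excluded for that count. With the block and the preset correlation 2 of 32 swaps moved the real 12 (highest other 12), and chance cannot be excluded. With the block and an estimated correlation 1 of 32 swaps, the real one, moved 7 (highest other 0), which argues against chance. With the GC correction and the preset correlation 1, the real one, moved 12 (highest other 11), hardly more than another swap. A share of 1 of 32 is the smallest that the swaps can give, and several counts were tried, so chance is not excluded for either. The count of lists was 3 with an estimated correlation and no block, and 0 with the block, GC correction and an estimated correlation.

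The 20 most abundant genes took 20.6% of counts in DMSO replicate 1 (others 18.3 to 18.9%) and 22.2% in dasatinib replicate 1 (others 19.7 to 20.5%), each far from its group. Among named genes, 14 of 238 groups of 6 held a library far from the others on the log2 scale, where chance gives about 11.9. In dasatinib replicate 5 these were CASP4 at 10.7 CPM, CEBPA at 33.4, GPD1 at 8.85, JPH2 at 39.1 and MYH11 at 6.89. In dasatinib replicate 2 they were CXCL2 at 2.41, CXCL3 at 3.73 and KRT19 at 21.7 CPM. In dasatinib replicate 4 they were EFNB2 at 3.19 and GDF15 at 357.6 CPM, and in dasatinib replicate 6 FOSL1 at 53.7 CPM. In DMSO libraries they were GLA at 36.8 CPM in replicate 5, and MMP1 at 1.75 and TUBA1C at 309.6 CPM in replicate 4.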

How the results depend on the processing

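The GC correction, the alternatives to it, fry in that fit and the fits without dasatinib replicate 5 were chosen after the data were seen, and the rest before. Without pairing, edgeR called 0 genes with RLE, no filter, the stricter filter and without dasatinib replicate 5 (262, 1924, 176 and 256 at an unadjusted p under 0.05), and 0 without each replicate number (136 to 301). limma-voom called 0 (221, and 1611 with quality weights). DESeq2 called 1 gene, and with the replicate block 112. The replicate block in edgeR gave 0, and with the GC correction 110. The cause of the gap between DESeq2 and edgeR was not tested.

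For genes changed by dasatinib, paired and GC-corrected, the count was 415 with no filter on low counts, 179 with a length curve added, 0 with no replicate block and 0 with no GC correction, and 0 to 120 without one replicate number (0 without 2 or 4, 34 without 1, 45 without 3). The counts were 76 and 78 with the GC curve centred and TMM or RLE, 136 with the stricter filter, 85 with limma-voom and 123 without dasatinib replicate 5. None of the 110 genes changed direction in these fits. Leaving out a replicate number leaves fewer degrees of freedom, equally for each number. This alone does not account for counts that run from 0 to 120, so the calls depend on which number is left out. Otherwise the cause was not tested. RLE scaling with the curve not centred is no test of this fit, since the curve resets the level.

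The 11 lists became 3 with an estimated correlation, 1 with fry, 7 with the replicate block and an estimated correlation, and 0 with the GC correction added to these. The 1 with fry was that of SRF and YAP targets. fry with the replicate block and GC correction gave 10 (5 up, 5 down), and it does not compare a list with other genes. Leaving out replicate numbers gave 8 to 12. No list past the threshold changed direction. Against the fit without pairing, which called 0 of the 121 named genes, 98 of 2043 values under alternatives came past the threshold, 0 of them in the other direction. The share of the 20 most abundant genes differed by 1.62 to 1.86 percentage points without one replicate number and passed without replicate 1 (1.74). Paired, it had an exact permutation p = 0.0312, the smallest that 6 pairs can give, and an adjusted p = 0.156. The median of all genes moved by under 0.1 (log2) with RLE (0.0052 against 0.0177). Low counts limit MKI67, CSF3 and LMNB1, which lie near 1 CPM.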

Other observations

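The percentile of the tubulin genes was a test written before its result was seen. Alpha and beta tubulins, the subunits of microtubules, were not among the lists, and 7 of 11 tested genes of that family rose. TUBB6 rose by 0.50 ± 0.05, TUBB by 0.49 ± 0.05, TUBA1B by 0.55 ± 0.07, TUBA1C by 0.50 ± 0.07, TUBA1A by 0.49 ± 0.09, TUBB2A by 0.39 ± 0.05 and TUBB4B by 0.36 ± 0.06. TUBB6 went from 264 ± 28.7 to 366 ± 50.1 CPM (SD, n = 6), higher in 6 of 6 pairs. All 7 passed with the GC curve centred and either TMM or RLE, 0 passed without replicate 2 or without replicate 4, and DESeq2 with the block did not call TUBB2A and TUBB4B (adjusted p = 0.13 and 0.48).

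The hypothesis that tubulin genes move as a family was tested on the 4 that did not pass (TUBA4A, TUBB2B, TUBB3 and TUBB4A). Their median log2 fold change of 0.48 lay at percentile 99.8 of 10000 random lists matched on expression, which is consistent with a change across the family. Near-identical copies share reads, and the counting tool is not given in the sources used here, so the members may not be independent.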
